A study of Homo sapiens with 18 samples.

How the data were processed

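The series measured messenger RNA in primary normal human lung fibroblasts, the cells that make the collagen-rich matrix of the lung. Cells received 1 of 3 small interfering RNA (siRNA) reagents, short duplexes that direct the breakdown of a matching transcript. These were a non-targeting control (siControl) and 2 siRNAs against MTHFD2, named siMTHFD2-9 and siMTHFD2-11 in the labels. Cells of each kind were left untreated or treated with transforming growth factor beta (TGF-β), a cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. Per the labels' protocols, the medium held 0.1% bovine serum albumin, 5.5 mM glucose, 2 mM glutamine and 1 mM pyruvate, with 24 h given as a time in that medium. The 6 groups held 3 libraries each, 18 in all. Libraries were directional and made from polyadenylated RNA captured with oligo-dT, per the labels' protocols, so transcripts without a poly(A) tail were under-represented.

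The deposited table gave a length-scaled transcript abundance (TPM) for each gene and library, computed by the authors with kallisto 0.46.1 on the human genome build GRCh38 (hg38), per the submitters' processing notes. The annotation release behind the table was not given in the sources used here. TPM divides the estimated fragments of a transcript by its length and scales each library to a fixed total, so a gene's value is its share of the library. A large rise of a few abundant genes therefore lowers the TPM of the rest, and no spike-in was used here to measure that. The table held 19756 genes, 1 of them without a symbol, and 1637 were listed at 0 in every library. The listed values of a library summed to between 839533 and 877931, so 12.2% to 16.1% of each library's total belonged to features not listed. No gene of the mitochondrial genome was listed. TPM keeps no record of sequencing depth. Depth was therefore unknown, and no interval or detection limit that needs it was computed.

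Gene symbols and Ensembl identifiers were used as the table paired them. Of the identifiers, 18356 were found in the gene name table used here and 1399 were not, 679 of them among the genes tested. Positions of 6 genes were taken from GENCODE release 29 on GRCh38. Among the genes tested, 44 entries in 22 pairs had identical values in every library, and their values were treated as uncertain. None of them is named in the results.

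Values were transformed as log2(TPM + 1), a scale that understates fold changes of low genes. Genes with a TPM of 1 or more in at least 3 libraries were tested, 12828 in all. One limma-trend model (limma 3.58.1 in R 4.3.3) with a mean for each of the 6 groups gave all contrasts with 12 residual degrees of freedom. All groups thus shared 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. Adjusted p-values of single genes below come from this limma model. The contrasts were TGF-β against untreated cells for each siRNA, each MTHFD2 siRNA against siControl in each treatment, the difference between TGF-β responses (the interaction), and siMTHFD2-11 minus siMTHFD2-9. A gene was counted as changed by both siRNAs when it was called with each in the same direction. MTHFD2 was also tested with an exact two-sided permutation test of TPM.

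The main design, the processing alternatives, 29 gene lists of 510 genes and the rule for naming genes were chosen before the data were examined. The lists covered extracellular matrix, contraction, TGF-β and bone morphogenetic protein (BMP) signalling, folate and amino acid metabolism, stress responses, energy metabolism, the cell cycle, inflammation and markers of other cell types. Lists with 3 or more tested genes, 26 of them, were tested with limma's camera, which compares a list with all other genes, at the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The list p-values were adjusted over the 26 lists. Below, an adjusted p of a list is the camera value at the preset correlation unless stated. Limma's fry, which asks whether the genes of a list move at all, was run on the same lists. The rule named MTHFD2 and 17 fixed genes of the matrix and of folate, serine, proline and asparagine metabolism in every comparison. It added up to 4 called members per list with the largest log2 fold change, and the 5 most increased and 5 most decreased genes with a mean TPM of 5 or more. Values had to be apart between the groups, and for the siRNA comparisons the gene had to be called with both siRNAs. Genes outside the rule were chosen after their values were seen and are named as such.

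The alternatives were a pseudocount of 0.1, no filter on low values, a stricter filter (TPM of 5 or more in at least 3 libraries), rescaling by the median ratio, quantile normalization, a fit of only the libraries compared, the replicate number as a block, limma array weights, and each library left out in turn. The replicate numbers of the labels were not treated as pairing the libraries. Chance was examined by refitting the same contrasts after reassigning libraries to groups, in all 10 splits of 3 against 3 libraries or in 100 drawn splits otherwise. Because both MTHFD2 siRNAs were compared with the same siControl libraries, all groups, siControl among them, were simulated as unchanged in 20 draws. Called genes were counted in 5 further draws of that kind. The fit was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. For siMTHFD2-9 in TGF-β treated cells it recovered 84 and 100 of them, with 11 other genes called. In a simulation with 1 list, the collagen chains, shifted by 0.5 on the log2 scale, camera called 1 of 26 lists, the shifted one. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The siRNA sequences were not used here.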

Results

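The 18 libraries formed 6 groups of 3: siControl, siMTHFD2-9 and siMTHFD2-11 fibroblasts, each untreated or treated with TGF-β. Between 11967 and 12477 genes per library had a TPM of 1 or more. Pearson's r across genes between libraries of 1 group, on the log2 scale, was 0.991 to 0.996. The first principal component held 82.3% of the variance and the second 3.9%. Ribosomal protein genes took 20.9% of the listed TPM in the siControl untreated library 2, against 18.7% and 18.8% in the other siControl untreated libraries. They took 16.7% to 18.5% in the untreated libraries of the MTHFD2 siRNAs, all below the siControl ones, and 13.2% to 14.1% in the TGF-β treated libraries. The labels do not say whether the libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

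MTHFD2 (ENSG00000065911), the targeted gene, encodes the mitochondrial methylenetetrahydrofolate dehydrogenase and cyclohydrolase of one-carbon metabolism. It is a protein-coding gene on the forward strand of chromosome 2, at 74198562 to 74217565 (GRCh38, GENCODE 29). In untreated cells MTHFD2 was at 53.2 ± 1.21 TPM (SD, n = 3) with siControl, 12.6 ± 1.40 with siMTHFD2-9 and 5.98 ± 0.894 with siMTHFD2-11. In TGF-β treated cells it was at 457 ± 9.49, 74.2 ± 1.27 and 41.2 ± 2.12 TPM in the same order. The siRNAs left 23.7% and 11.2% of the siControl level of MTHFD2 in untreated cells, and 16.2% and 9.01% with TGF-β. MTHFD2 thus fell, with log2 changes of -2.00 and -2.96 in untreated cells and -2.61 and -3.44 in TGF-β treated cells. MTHFD2 was lower with siMTHFD2-11 than with siMTHFD2-9, by a log2 difference of -0.97 in untreated and -0.84 in treated cells, both called by limma. In each of these comparisons the values of the 3 libraries of a group lay apart from those of the other, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. MTHFD2 was called in each of these comparisons under every alternative tried.

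**Figure D1:**
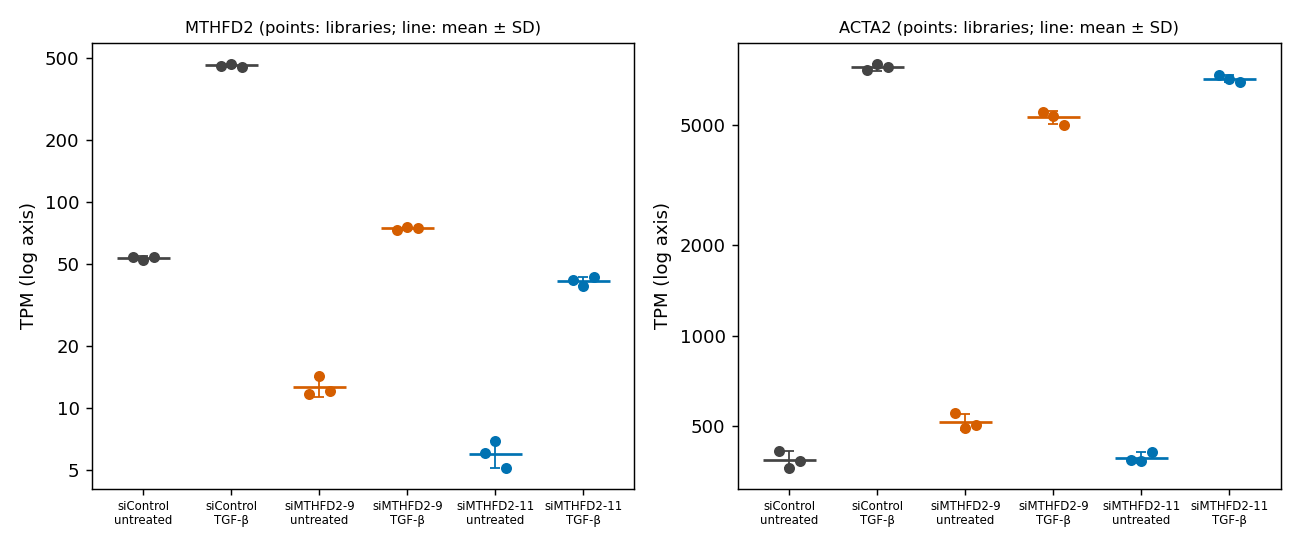
TPM of MTHFD2 and of ACTA2, on a log axis, in each of the 18 libraries (points), with the mean and SD of each group of 3. MTHFD2 rose with TGF-β from 53.2 to 457 TPM with siControl and was lower with both siRNAs, and ACTA2 rose from 387 to 7804 TPM with siControl and to 5309 TPM with siMTHFD2-9.

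The first comparison asked how siControl fibroblasts responded to TGF-β. Genes of the contractile apparatus rose together: ACTA2, smooth muscle α-actin and the usual mark of a myofibroblast, went from 387 ± 25.1 to 7804 ± 207 TPM (SD, n = 3; log2 4.33). ACTA2 lies on the reverse strand of chromosome 10, at 88935074 to 88991339. The collagen-binding integrin chain ITGA11 (log2 4.54), the smooth muscle γ-actin ACTG2 (3.98) and the tropomyosin TPM1 (3.56) rose as well. Of 22 contractile genes tested, 21 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 3.4e-13, and 0.0324 with an estimated correlation). Collagen chains also rose. COL1A1 (chromosome 17, 50183289 to 50201632) went from 1542 ± 212 to 11350 ± 408 TPM (log2 2.89), and COL1A2 (chromosome 7, 94394561 to 94431232) from 3356 ± 156 to 7131 ± 125 (log2 1.09), the 2 chains of type I collagen. COL3A1, the chain of type III collagen, rose by 1.08, and COL10A1 (4.28), COL11A1 (3.58) and COL4A1 (3.02) rose more. Of 23 collagen chains, 17 rose and 6 fell, the same adjusted over the list alone (adjusted p = 2.29e-06, and adjusted p = 0.165 with an estimated correlation).

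Genes that build and crosslink the matrix rose with TGF-β. The crosslinking oxidases LOX (log2 2.56), LOXL2 (2.32) and LOXL4 (1.73) and the lysyl hydroxylase PLOD2 (2.42) were among 20 collagen modification genes that rose of 27 tested, while 4 fell (21 and 4 adjusted over the list alone; adjusted p = 2.01e-07, and adjusted p = 0.103 with an estimated correlation). Of 24 matrix glycoproteins and proteoglycans, 18 rose and 5 fell, also when adjusted over the list alone. These included COMP (6.37), the elastin gene ELN (5.38), the proteoglycan BGN (3.43), THBS2 (3.32) and the fibronectin gene FN1 (2.48). The list's adjusted p was 3.03e-06, and the adjusted p = 0.0985 with an estimated correlation. Early targets of TGF-β signalling rose in 15 of 20 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 3.03e-06, and adjusted p = 0.165 with an estimated correlation). Among them were the NADPH oxidase NOX4 (4.71), PMEPA1 (3.13) and TGFBI (2.79). Of 12 targets of the mechanosensitive coactivators YAP and TAZ, 9 rose, also adjusted over the list alone, with CCN1 at 2.30 and ANKRD1 at 1.72 (adjusted p = 0.00012, and adjusted p = 0.103 with an estimated correlation).

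Genes of amino acid and one-carbon metabolism rose as well. PSAT1 (log2 3.80), PSPH (2.24) and PHGDH (1.95), the enzymes of serine synthesis from glycolysis, and SHMT2 (1.60), which makes glycine in mitochondria, rose, 4 of 5 genes of their list (adjusted p = 0.000269, and 0.0324 with an estimated correlation). MTHFD2 itself rose by 3.08. In the mitochondrial folate pathway 8 of 10 genes rose and 1 fell (adjusted p = 0.00144, and adjusted p = 0.0985 with an estimated correlation), including ALDH1L2 (1.99), MTHFD1L (0.72) and MTHFD2L (0.64). The cytosolic enzyme MTHFD1 rose by 0.26, and 11 of the 20 genes of cytosolic folate, methionine and nucleotide metabolism rose while 3 fell (adjusted p = 0.112), the thymidylate synthase gene TYMS by -1.53. ATF4, the transcription factor of the amino acid stress response, rose by 0.62. In its list 24 of 29 genes rose and 3 fell, among them CHAC1 (4.17), the asparagine synthetase ASNS (3.47) and the amino acid transporter SLC7A5 (3.40; adjusted p = 4.78e-11, and 0.0324 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose in 17 of 20 cases and fell in 1, with GARS1 at 1.98 and IARS1 at 1.92 (adjusted p = 3.84e-09, and 0.0324 with an estimated correlation). The proline synthesis enzymes PYCR1 (2.06) and ALDH18A1 (1.02) were among 8 of 10 genes of proline and glutamate synthesis that rose, while 2 fell (adjusted p = 0.00366, and adjusted p = 0.135 with an estimated correlation). Chaperones and folding enzymes of the endoplasmic reticulum unfolded protein response rose in 15 of 16 cases, with XBP1 at 1.42 (adjusted p = 2.29e-06, and 0.0324 with an estimated correlation). Adjusted over the list alone, each of these 7 lists gave the same counts.

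In the lists of matrix proteases and inhibitors and of BMP and ID genes, more genes fell than rose. The plasminogen activator PLAT (log2 -2.09), the collagen-degrading cathepsin CTSK (-1.96) and the protease inhibitor TIMP4 (-1.58) were among 13 of 20 matrix proteases and inhibitors that fell, while 5 rose (adjusted p = 0.00844, and adjusted p = 0.197 with an estimated correlation). BMP4 (-2.42) and the BMP target ID1 (-1.69) were among 6 of 10 BMP and ID genes that fell, and none rose (adjusted p = 0.00771, and adjusted p = 0.184 with an estimated correlation). Of 12 inflammatory genes 8 fell and 2 rose, with the chemokine CXCL12 at -3.39 and the cytokine LIF at 1.73 (adjusted p = 0.0239, and adjusted p = 0.103 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same. Of all genes, the largest increases were in IGFBP3 (8.19), which binds insulin-like growth factors, the lubricin gene PRG4 (7.34), COMP, the keratin KRT7 (6.17) and PI16 (5.47). The largest decreases were in the alcohol dehydrogenase ADH1B (-6.97), NPTX1 (-5.03), FGL2 (-4.81), OMG (-4.73) and IGSF10 (-4.66).

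Genes of glycolysis rose in 13 of 21 cases and fell in 3 (13 and 4 adjusted over the list alone), with the glucose transporter SLC2A1 at 2.28 (adjusted p = 0.00605, and adjusted p = 0.269 with an estimated correlation). Other lists had members on both sides and did not pass camera: cholesterol synthesis (9 rose and 4 fell of 20; adjusted p = 0.349), cell cycle (9 and 3 of 26; 0.337), p53 targets (4 and 8 of 18, or 4 and 9 adjusted over the list alone; 0.0838), interferon response (5 and 7 of 23; 0.625), nuclear subunits of oxidative phosphorylation (9 and 9 of 32; 0.942) and NRF2 targets (5 and 7 of 16; 0.694). Within them the cyclin CCNA2 rose by 2.00, the replication factor MCM4 changed by -1.02, and the ferritin genes FTH1 and FTL by -1.72 and -1.66. Except for the p53 targets, these counts were the same adjusted over the list alone. Fibroblast markers rose in 4 cases and fell in 6 of 10 (adjusted p = 0.47), with TCF21 at -3.21 and S100A4 at -2.14. Among markers of other cell types, 1 of 4 epithelial genes rose and 2 fell (adjusted p = 0.848), with KRT18 at 2.29, and 4 of 5 pericyte and mesothelial genes rose and 1 fell, with MCAM at 3.35 (adjusted p = 0.0254, and adjusted p = 0.173 with an estimated correlation). These marker counts, too, were the same adjusted over the list alone. Fewer than 3 endothelial and fewer than 3 immune marker genes were tested, so these lists were not, and the macrophage and lysosome gene CD68 changed by -1.68. The list of mitochondrially encoded genes was not analysed here.

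In all, limma called 7971 of 12828 genes with TGF-β in siControl cells, 3916 higher and 4055 lower, of which 1707 changed at least 2-fold. The median log2 change of all genes was -0.01. In siMTHFD2-9 cells TGF-β changed 7429 genes (3257 higher, 4172 lower) and in siMTHFD2-11 cells 8240 genes (3637 higher, 4603 lower). After quantile normalization more were higher than lower, 4128 and 3960 with siControl, 3952 and 3744 with siMTHFD2-9 and 4352 and 4006 with siMTHFD2-11. With siControl this was also so with the stricter filter (3567 and 3294) and without siControl untreated library 1 or 3 (3955 and 3677, 3811 and 3672). ACTA2 rose by 3.36 in siMTHFD2-9 and by 4.18 in siMTHFD2-11 cells, COL1A1 by 2.64 and 2.72, FN1 by 2.19 and 2.41, and PSAT1 by 3.31 and 3.66. Of the genes called in siControl cells, 96.9% had a change of the same sign in siMTHFD2-9 cells and 97.9% in siMTHFD2-11 cells. Across genes, which are not independent replicates, the slope of the response against that of siControl cells was 0.849 with siMTHFD2-9 and 0.991 with siMTHFD2-11 (Pearson's r 0.947 and 0.965, Spearman's rho 0.910 and 0.931). With each library left out in turn, the slopes stayed between 0.831 and 0.861 and between 0.971 and 1.01.

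The next comparisons asked what loss of MTHFD2 changed in untreated fibroblasts. With siMTHFD2-9 and siMTHFD2-11 alike, OLFM2 (log2 1.11 and 0.63), the granulin precursor GRN (0.62 and 0.58), CERS4 (0.70 and 0.58), TUBA4A (0.91 and 0.53) and LYNX1 (0.89 and 0.51) rose. CYB5R4 (-0.67 and -0.67), PCOLCE2 (-0.80 and -0.62), the splicing factor SNRPD1 (-0.61 and -0.73), the interferon regulatory factor IRF1 (-0.58 and -0.57) and the ribosomal protein gene RPL22L1 (-0.62 and -0.51) fell with both. Amino acid transporters of the ATF4 list, SLC1A4 (0.43 and 0.57), SLC6A9 (0.39 and 0.56) and SLC7A5 (0.39 and 0.40), and the stress sensor SESN2 (0.41 and 0.36) rose with both siRNAs. ATF4 itself differed by 0.09 and 0.09, SHMT2 by 0.06 and 0.18, PHGDH by -0.10 and 0.19, and PSAT1 by 0.25 and 0.17, and none of these passed. CDK1, the kinase that drives entry into mitosis, fell (-0.95 and -0.56), and CDKN1A, which encodes the cell cycle inhibitor p21, rose (0.86 and 0.34). The matrix gene POSTN fell (-0.67 and -0.36). Genes of the matrix and collagen lists that rose with both included FBLN2 (0.38 and 0.39), BGN (0.25 and 0.44) and P4HA3 (0.29 and 0.39). COL4A2 (0.39 and 0.28) and CTSK (0.34 and 0.32) rose too. COL1A1 (0.24 and 0.27) and COL1A2 (-0.03 and 0.04) did not pass.

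Both siRNAs changed 259 genes in the same direction, 212 higher and 47 lower, and 4 in opposite directions, where independent lists of these sizes would share 34.9 and 3.88. The count with both rested on the 438 genes called with siMTHFD2-11 (350 higher, 88 lower), and these counts were unstable. With only the libraries compared in the fit, 2 genes were called with siMTHFD2-11 and 1 with both, and without filter, with median-ratio rescaling or with array weights the counts were 221, 227 and 2007 with siMTHFD2-11 and 140, 135 and 668 with both. Leaving out siControl untreated library 1, 2 or 3 gave 1073, 23 or 55 genes with siMTHFD2-11 and 692, 16 or 41 with both, and leaving out siMTHFD2-11 untreated library 2 or 3 gave 5 or 29 and 3 or 20. Without that siMTHFD2-11 library 2, only MTHFD2 and SLC1A4 of the genes named as changed by both siRNAs were still called with siMTHFD2-11. Calls with siMTHFD2-9 ended with only the libraries compared for IRF1, SNRPD1, SESN2, SLC1A4, SLC6A9, SLC7A5, FBLN2, BGN and P4HA3. They also ended without siControl untreated library 2 for IRF1 (-0.45), SLC6A9 (0.24), SLC7A5 (0.29), FBLN2 (0.27) and BGN (0.17). Without siMTHFD2-9 untreated library 2 they ended for the same genes (-0.48, 0.36, 0.31, 0.34 and 0.23). Without siMTHFD2-9 untreated library 3 they ended for SLC6A9 (0.37) and BGN (0.22), and with array weights for SLC6A9 (0.29). The share of called genes that were higher with siMTHFD2-11 was 79.9%, and 66.1% after median-ratio rescaling or 59.7% after quantile normalization.

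Among gene lists in untreated cells, the ATF4 list rose with siMTHFD2-11, 10 of 29 genes higher and none lower (17 and 1 adjusted over the list alone; adjusted p = 3.31e-07, and adjusted p = 0.263 with an estimated correlation). With siMTHFD2-9 7 of its genes rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0343, and adjusted p = 0.558 with an estimated correlation). Cell cycle genes fell with siMTHFD2-9, 10 of 26 lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 5.12e-08, and 0.0103 with an estimated correlation). With siMTHFD2-11 1 of the 26 fell (2 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.263 with an estimated correlation). Glycolysis genes rose in 9 of 21 cases with siMTHFD2-9 (11 adjusted over the list alone; adjusted p = 0.000648, and adjusted p = 0.273 with an estimated correlation) and in 4 with siMTHFD2-11 (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00418, and adjusted p = 0.459 with an estimated correlation).

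Against siControl in untreated cells, siMTHFD2-9 changed 1844 genes, 1279 higher and 565 lower, of which 263 were also called with siMTHFD2-11. The strongest changes, in genes chosen after their values were seen, included GSN, the gene of the actin-severing protein gelsolin (chromosome 9, 121207794 to 121332843). GSN was at 424 ± 42.1 TPM (SD, n = 3) with siControl and 124 ± 5.91 with siMTHFD2-9 (log2 -1.76), and at 511 ± 30.1 with siMTHFD2-11 (0.27, called, although not without siControl untreated library 2 or 3, where it was 0.19 or 0.29, or siMTHFD2-11 untreated library 2 or 3, 0.23 or 0.26, nor without filter, after median-ratio rescaling (0.22) or quantile normalization (0.25), with only the libraries compared or with the replicate block). The lysosomal thioesterase PPT1 fell (-1.24), and CLCA2 (1.04), the heparan sulfatase SULF2 (1.00), the matrix protein TNC (0.84) and the urokinase gene PLAU (0.63) rose, again chosen after their values were seen. Contractile genes rose in 12 of 22 cases (15 adjusted over the list alone; adjusted p = 1.32e-06, and adjusted p = 0.246 with an estimated correlation), ACTA2 by 0.42 and, chosen after its value was seen, the smooth muscle myosin MYH11 by 0.68. Pericyte and mesothelial markers rose alongside in 4 of 5 cases, also adjusted over the list alone (adjusted p = 0.00771, and adjusted p = 0.246 with an estimated correlation). Targets of the tumour suppressor p53 rose in 10 of 18 cases (13 higher and 1 lower adjusted over the list alone; adjusted p = 4.96e-05, and adjusted p = 0.246 with an estimated correlation), among them CDKN1A and, chosen after their values were seen, FDXR (0.67) and the death receptor TNFRSF10B (0.48).

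Collagen modification genes rose in 13 of 27 cases with siMTHFD2-9 in untreated cells (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.44e-05, and adjusted p = 0.246 with an estimated correlation), with LOXL2 at 0.50. PYCR1 rose by 0.34. The count of 1844 was 448 with only the libraries compared in the fit, where PYCR1 no longer passed, and 1055 without siControl untreated library 2. Of the called genes 69.4% were higher, and 55.1% after quantile normalization.

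In TGF-β treated cells siMTHFD2-9 lowered many contractile genes and raised many members of the list of matrix proteases and inhibitors. ACTA2 was at 7804 ± 207 TPM (SD, n = 3) with siControl and 5309 ± 265 with siMTHFD2-9 (log2 -0.56). Contractile genes chosen after their values were seen were the myosin light chain kinase MYLK (-0.74), the smooth muscle myosin MYH11 (-0.63) and calponin CNN1 (-0.56), and outside the list the troponin TNNT2 (-1.25). Of 22 contractile genes 12 fell and none rose (15 adjusted over the list alone; adjusted p = 1.4e-12, and 0.0284 with an estimated correlation). The interstitial collagenase MMP1 (chromosome 11, 102789920 to 102798160) was at 61.3 ± 7.22 TPM with siControl and 200.1 ± 12.6 with siMTHFD2-9 (1.69). MMP1, PLAU (1.09), ADAMTS8 (0.89) and MMP14 (0.41) were chosen after their values were seen, among 13 of 20 matrix proteases and inhibitors that rose (15 adjusted over the list alone; adjusted p = 4.88e-18, and 0.00452 with an estimated correlation). Cell cycle genes fell in 10 of 26 cases and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 9.04e-08, and 0.00807 with an estimated correlation). Of these, CDC20 (-0.86), CCNA2 (-0.68) and the topoisomerase TOP2A (-0.64) were chosen after their values were seen. The p53 targets rose in 9 cases and fell in 1 of 18 (11 and 1 adjusted over the list alone; adjusted p = 2.59e-08, and adjusted p = 0.0633 with an estimated correlation).

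GSN and PPT1 were lower in TGF-β treated cells too, GSN at 380 ± 4.85 TPM with siControl and 120 ± 10.5 with siMTHFD2-9 (SD, n = 3; log2 -1.66) and PPT1 at -0.97. Also chosen after their values were seen, CLCA2 (1.69), the lipoprotein lipase inhibitor ANGPTL4 (1.67), SULF2 (1.31), the stress cytokine GDF15 (0.96) and TNC (0.68) rose, and ANKRD44 (-1.71) and the cell cycle kinase CDK6 (-1.09) fell. COL1A1 (0.00) and COL1A2 (-0.10) did not pass, and of 23 collagen chains 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.746). FN1 (-0.23), COL3A1 (-0.28), PHGDH (-0.26) and ASNS (-0.35) fell, while ATF4 (-0.13), PSAT1 (-0.24), SHMT2 (-0.18), MTHFD1L (-0.13) and PYCR1 (-0.07) did not pass. The FN1 call ended after median-ratio rescaling (-0.20), without filter (-0.23), without siControl TGF-β library 2 or 3 (-0.22 each) and without siMTHFD2-9 TGF-β library 1, 2 or 3 (-0.24, -0.24 and -0.20). The COL3A1 call ended without siControl TGF-β library 2 (-0.27) or siMTHFD2-9 TGF-β library 3 (-0.25) and after quantile normalization (-0.22), and that of PHGDH without siControl TGF-β library 1 or 3 (-0.23 and -0.25) or siMTHFD2-9 TGF-β library 3 (-0.18) and after median-ratio rescaling (-0.23).

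In all, siMTHFD2-9 changed 1052 genes in TGF-β treated cells, 588 higher and 464 lower. The count was 646 without siControl TGF-β library 2, 673 without library 3, 658 without siMTHFD2-9 TGF-β library 2, and 2195 with array weights. More genes were lower than higher with only the libraries compared (769 and 731) and with array weights (1125 and 1070). With siMTHFD2-11 limma called 1 gene, MTHFD2 itself, and 666 genes had an unadjusted p below 0.05. The count was 2 without siControl TGF-β library 2 or siMTHFD2-11 TGF-β library 3 and 13 with array weights. In simulated data of the same size, 77 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold were recovered for this comparison. Smaller changes were not simulated, so the power for them is not known. The genes called with siMTHFD2-9 in TGF-β treated cells had a median absolute log2 change of 0.41, less than 1.5-fold. ACTA2 (-0.13), COL1A1 (0.10), FN1 (-0.02), PHGDH (0.01) and PSAT1 (0.03) did not pass with siMTHFD2-11, and neither did MMP1 (-0.50) or GSN (0.07). None of the 22 contractile genes passed over all genes, while 4 fell when adjusted over the list alone (adjusted p = 8.41e-05, and adjusted p = 0.624 with an estimated correlation). MTHFD2 was therefore the 1 gene changed by both siRNAs with TGF-β.

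The interaction asked whether the response to TGF-β itself differed with loss of MTHFD2. With siMTHFD2-9 it differed for 286 genes, 103 with a more positive and 183 with a more negative change than in siControl cells. The response was lower for ACTA2 (log2 -0.97) and, chosen after their values were seen, for MYH11 (-1.31), TNNT2 (-1.22), SYNPO2 (-1.02), CNN1 (-0.83) and MYLK (-0.64). In the contractile list it was lower for 13 of 22 genes and higher for none (19 adjusted over the list alone; adjusted p = 6.52e-24, and 0.00653 with an estimated correlation). ACTA2, MYH11 and CNN1 were higher than with siControl in untreated siMTHFD2-9 cells and lower in treated ones, so both differences enter these values, although the untreated CNN1 call (0.27) ended with only the libraries compared in the fit. The response was higher for MMP1 (1.23) and ANGPTL4 (1.08), both chosen after their values were seen, and 5 of 20 matrix proteases and inhibitors were higher (7 adjusted over the list alone; adjusted p = 2.91e-09, and 0.0354 with an estimated correlation). MTHFD2 rose less (-0.61), and so did PSAT1 (-0.49), while COL1A1 (-0.25), FN1 (-0.29), SHMT2 (-0.24) and ASNS (-0.19) did not pass. The slope over all genes was 0.849 with siMTHFD2-9, so large responses tended to be smaller, and the differences given here include that. Genes of serine and glycine synthesis, PSAT1 among them, lay above the line fitted to all genes by a median of 0.137, with 1 of 5 below it. The PSAT1 call ended with only the libraries compared in the fit and without any 1 of 10 of the 12 libraries compared (-0.40 to -0.51).

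With siMTHFD2-11 limma called no gene whose response differed, and 1636 had an unadjusted p below 0.05. The count was 218 with array weights and 25 without siControl untreated library 1. In simulated data 45 of 100 genes changed 1.5-fold and 94 of 100 changed 2-fold were recovered, and smaller changes were not simulated. The difference was -0.15 for ACTA2, -0.17 for COL1A1, -0.08 for FN1 and -0.48 for MTHFD2. No gene was called with both siRNAs. The ATF4 list, with no gene called (7 lower adjusted over the list alone), had an adjusted p = 0.00144, and adjusted p = 0.703 with an estimated correlation. For siMTHFD2-9 the count of 286 was 165 with only the libraries compared in the fit, 486 with array weights, 512 without siControl untreated library 1, 156 without siControl TGF-β library 2, 528 without siMTHFD2-9 untreated library 3, and 189 or 154 without siMTHFD2-9 TGF-β library 1 or 2. Of these genes 36.0% had the more positive change, against 51.3% after median-ratio rescaling and 47.4% after quantile normalization.

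**Figure D2:**
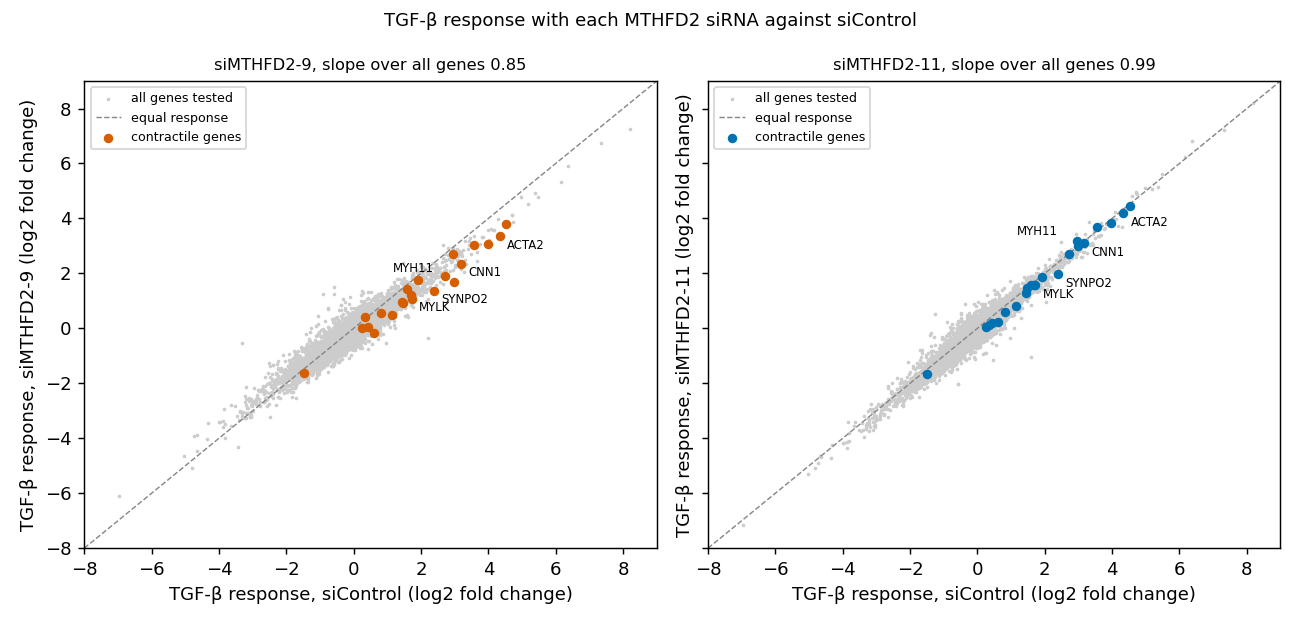
Log2 change with TGF-β in siMTHFD2-9 (left) and siMTHFD2-11 cells (right) against that in siControl cells, for all 12828 genes (grey) and the 22 contractile genes (coloured), with a dashed line of equal response. Contractile genes, ACTA2 among them (4.33 in siControl, 3.36 in siMTHFD2-9 and 4.18 in siMTHFD2-11 cells), lie mostly below the line with siMTHFD2-9.

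The siRNAs were also compared with each other, siMTHFD2-11 minus siMTHFD2-9, in cells of the same treatment. In untreated cells 771 genes differed (323 higher and 448 lower with siMTHFD2-11), and in TGF-β treated cells 979 (340 and 639). With TGF-β the largest differences among genes chosen after their values were seen were in MMP1 (log2 -2.20), ANGPTL4 (-1.80), GSN (1.73), ANKRD44 (1.42), CLCA2 (-1.40) and SULF2 (-1.16). In untreated cells GSN (2.03), PPT1 (1.33) and CLCA2 (-1.07) differed most among the same genes. In treated cells 14 of 20 matrix proteases and inhibitors were lower with siMTHFD2-11 and none higher (17 adjusted over the list alone; adjusted p = 1.02e-19, and 0.00304 with an estimated correlation). Contractile genes were higher in 9 of 22 cases (10 adjusted over the list alone; adjusted p = 7.63e-08, and adjusted p = 0.0807 with an estimated correlation), and in untreated cells lower in 8 (13 lower and 1 higher adjusted over the list alone; adjusted p = 8e-09, and adjusted p = 0.12 with an estimated correlation). The untreated count was 257 with only the libraries compared in the fit, 470 or 505 without siMTHFD2-9 untreated library 1 or 2 (without library 2, 261 higher and 244 lower), and 447, 431 or 403 without siMTHFD2-11 untreated library 1, 2 or 3. The TGF-β count was 588 or 630 without siMTHFD2-9 TGF-β library 2 or 3, 471 without siMTHFD2-11 TGF-β library 2, and 1793 with array weights.

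**Figure D3:**
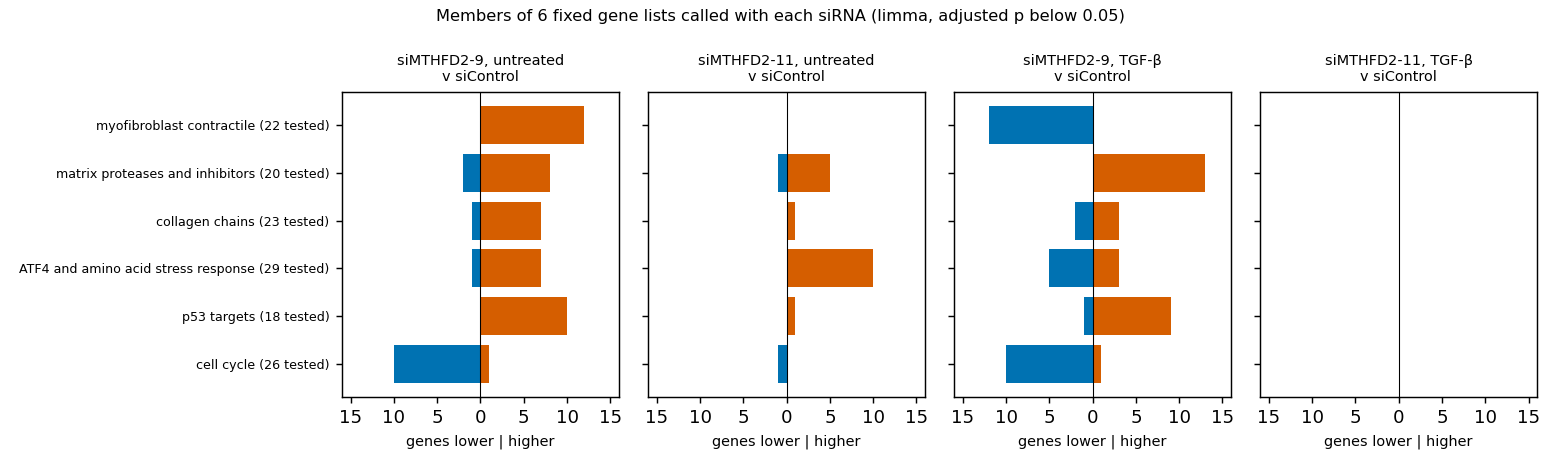
Number of genes called higher (right of 0) and lower (left of 0) in 6 gene lists for each siRNA against siControl, in untreated and TGF-β treated cells. With TGF-β, siMTHFD2-9 lowered 12 of 22 contractile genes and raised 13 of 20 matrix proteases and inhibitors, and with siMTHFD2-11 no gene of either list was called.

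Because both siRNAs were compared with the same siControl libraries, their log2 changes were correlated even without any effect. In untreated cells the correlation across genes was 0.515, against 0.497 for simulated unchanged groups, and in TGF-β treated cells 0.354 against 0.498. For the interaction it was 0.444 against 0.504. The covariance exceeded the simulated one by 0.0126 in untreated cells (0.0204 against 0.00784), by 0.00266 in treated cells (0.0105 against 0.00782) and by 0.00757 for the interaction (0.0236 against 0.0160). Changes had the same sign in 70.2% of genes in untreated cells (66.6% simulated), 62.6% in treated cells (66.6%) and 69.0% for the interaction (66.7%). In 5 further draws called genes were counted, and the simulated groups shared none. Those draws held no effect in any group, so few genes could be called at all. They do not show how much of the overlap seen in untreated cells came from shared controls. With 3 siControl libraries per treatment the controls could not be split into parts of 2 or more, and part of the overlap may come from them.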

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

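In this part the comparison of MTHFD2 levels between the siRNAs and both distances of contractile genes from the all-gene line were tests chosen after the results were seen, as were the 2 readings of tests named as such below. The results here drew attention because a test of the difference between groups was passed.

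The siRNAs differed from each other in 771 genes in untreated cells and 979 in TGF-β treated cells, and siMTHFD2-9 changed more genes than siMTHFD2-11, except with array weights in untreated cells (1603 against 2007). Stronger loss of MTHFD2 with siMTHFD2-9 was argued against, since MTHFD2 was lower with siMTHFD2-11, by a log2 difference of -0.836 in TGF-β treated cells, where the difference was the smaller. Scaling between libraries was argued against too, since 1282 genes were called with siMTHFD2-9 in TGF-β treated cells after median-ratio rescaling, against 1052. Repression of other transcripts that match the seed of siMTHFD2-9 stayed open: among 16012 7-mers ranked by how far genes carrying them in the 3' UTR fell, 21.7% of them in MTHFD2, the MTHFD2 7-mer that ranked best over both treatments together was at rank 5 in untreated and 38 in treated cells. That missed the top 10 set beforehand as the bound. With fold changes shuffled over genes, 19 of 20 7-mers lowered by 0.05 (log2) reached that bound in both treatments. Carriers of the real 7-mer differed by less on average, -0.02 in untreated and -0.012 in treated cells. That recovery therefore does not give the power for it. GSN, which fell most in untreated cells among the genes named apart from MTHFD2, had 0 sites of that 7-mer. PPT1 had 1 site, and CDK6 and ANKRD44 had 2 each. In treated cells the z of that 7-mer, -3.04, was within 1 unit of the -3.41 of the last 7-mer in the top 10. By that reading, chosen after the ranks were seen, the test was not taken to exclude such repression. Another MTHFD2 7-mer, TTTGTAT, ranked higher in untreated cells, at 2, but was at 156 in treated cells. It had 4 sites in CDK6, 3 in ANKRD44 and 0 in GSN and PPT1. For siMTHFD2-11 the MTHFD2 7-mer that ranked best over both treatments was at rank 33 in untreated and 510 in treated cells.

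All 10 splits of 6 libraries into 3 and 3 were too few for a share under 0.05. The highest other split of the siMTHFD2-11 and siMTHFD2-9 libraries gave 1 gene in untreated cells, against 771, and 0 in treated cells, against 979. The real split was the 1 of 10 with as many genes in each case.

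The response to TGF-β differed with siMTHFD2-9 for 286 genes, and the contractile genes ACTA2 (log2 -0.97), MYH11 (-1.31), SYNPO2 (-1.02), CNN1 (-0.83) and MYLK (-0.64) responded less. The contractile genes lay below the all-gene line by a median of -0.249 (SE 0.0497), with 17 of 22 below it. That met the bound for arguing against a weaker response of all TGF-β responsive genes, but does not decide the question. The list was taken up because its response was low, and the SE, a bootstrap over genes, holds no spread between libraries. Many contractile genes were also higher in untreated siMTHFD2-9 cells, which enters the distance. Whether loss of MTHFD2 had a part in the lower contractile response stayed open. With siMTHFD2-11, which lowered MTHFD2 further, the median distance was -0.0531 (SE 0.0374), less than 2 SE from the bound of -0.1. Of 100 splits of the libraries, 6 gave as many genes as the real one. The splits with more genes than the real one kept or exchanged siMTHFD2-9 and siControl whole in untreated cells, in TGF-β treated cells or in both. Differences between these groups within a treatment thus entered the interaction of those splits. The share therefore cannot decide whether the count of 286 arose by chance, and chance was not excluded. The highest other split gave 2497 genes, several times the real count, and exchanged siMTHFD2-9 and siControl in TGF-β treated cells alone, so it points to the structure of the samples, in which each treatment's groups differ.

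With siMTHFD2-9 the response also differed for TNNT2 (log2 -1.22), OLFM2 (-1.16), SLC1A4 (-0.68), MTHFD2 (-0.61) and COL4A2 (-0.49), which rose less with TGF-β than in siControl cells. In untreated cells OLFM2, SLC1A4 and COL4A2 were already higher with siMTHFD2-9 than with siControl, and POSTN was lower. Those untreated differences enter the values given here. CTSK fell with TGF-β in siControl cells (-1.96), so its positive difference means a smaller fall. The response was higher for MMP1 (1.23), ANGPTL4 (1.08), POSTN (0.91) and CTSK (0.35). It was also higher for CLCA2 (0.65), although the CLCA2 call ended with only the libraries compared in the fit and without siControl untreated library 2, siControl TGF-β library 2, siMTHFD2-9 untreated library 1 or siMTHFD2-9 TGF-β library 2 or 3 (0.59 to 0.63). ADAMTS8 (0.51) ended without filter, with the replicate block, and without siControl untreated library 1 or 3, siControl TGF-β library 1 or 2, siMTHFD2-9 untreated library 1 or 2, or siMTHFD2-9 TGF-β library 2 or 3 (0.44 to 0.54). PSAT1 (-0.49) ended without filter, with only the libraries compared, with the replicate block, and without any 1 of the libraries compared except siControl untreated library 1 and siMTHFD2-9 untreated library 3 (-0.40 to -0.51).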

How the results depend on the processing

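MTHFD2 kept its direction and side of the threshold in all 166 alternative fits, and the counts of genes changed by TGF-β stayed within 1.5 times of the main ones in every alternative. Of 226 alternative counts 173 stayed within 1.5 times and 53 did not, and the causes were not tested. With only the libraries compared in the fit, which leaves fewer residual degrees of freedom, the counts were 448 for siMTHFD2-9 and 2 for siMTHFD2-11 in untreated cells, 1 for both, 165 for the siMTHFD2-9 interaction and 257 for the difference between siRNAs in untreated cells. With array weights they were 2007 for siMTHFD2-11 and 668 for both in untreated cells; 2195, 13 and 7 for siMTHFD2-9, siMTHFD2-11 and both in TGF-β treated cells; 486, 218 and 51 for the interactions with siMTHFD2-9, siMTHFD2-11 and both; and 1793 for the difference between siRNAs in TGF-β treated cells. For siMTHFD2-11 and for both in untreated cells, the counts were 221 and 140 without filter, where more genes were tested, 227 and 135 with median-ratio rescaling, and 215 and 142 with the replicate number as a block, with 213 of the 215 among the 438. A pseudocount of 0.1 gave 2 genes for siMTHFD2-11 and 2 for both in TGF-β treated cells. With 1 library left out in turn, the counts for siMTHFD2-9, siMTHFD2-11 and both ranged over 1055 to 2150, 5 to 1073 and 3 to 692 in untreated cells. For siMTHFD2-9 and siMTHFD2-11 in TGF-β treated cells they were 646 to 750 and 1 to 2, for the interactions with siMTHFD2-9, siMTHFD2-11 and both 154 to 528, 0 to 25 and 0 to 11, and for the difference between siRNAs 403 to 1051 in untreated and 471 to 722 in treated cells. The replicate numbers did not pair the libraries: of 45 pairs with the same number, 1 had a correlation of residuals over 0.1. Of 7968 alternatives for named genes 7384 gave the same call, 359 ended a call, 93 added one, 132 moved a value that was not called, and none reversed one. The FN1 value of 0 under quantile normalization follows from its construction, since FN1 was the most abundant gene in both groups. Of 364 list results 143 were called in the main fit. An estimated correlation ended 115 of these calls, median-ratio rescaling 3 and the block 1. Of 1092 alternatives for gene lists 952 gave the same call, lists called in neither fit among them. Depth was unknown, so its limits could not be given.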

Other observations

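The mean of both siRNAs against siControl was planned beforehand for the list tests alone and not for counts of genes. It gave 1486 genes in untreated cells (1141 higher, 345 lower) and 184 in TGF-β treated cells (111 and 73). For the interaction 29 were higher and 72 lower. In untreated cells the ATF4 list rose in 14 of 29 cases (16 adjusted over the list alone; adjusted p = 0.000108, and adjusted p = 0.339 with an estimated correlation). Cell cycle genes fell in 8 of 26 cases and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 3.7e-06, and 0.029 with an estimated correlation), with CDK1 at -0.76. In TGF-β treated cells contractile genes fell in 6 of 22 cases (12 adjusted over the list alone; adjusted p = 2.89e-13, and 0.0221 with an estimated correlation), ACTA2 by -0.34. Matrix proteases and inhibitors rose in 5 of 20 cases (10 adjusted over the list alone; adjusted p = 2.89e-13, and 0.013 with an estimated correlation), although MMP1 was at 1.69 with siMTHFD2-9 and -0.50 with siMTHFD2-11, so a mean does not show an effect of both siRNAs.

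With siMTHFD2-9 in TGF-β treated cells, more lists held changed genes. Among NRF2 targets, which respond to oxidants, 5 of 16 rose, also adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.201 with an estimated correlation). Collagen modification genes rose in 8 of 27 cases and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 1.34e-05, and adjusted p = 0.201 with an estimated correlation), and matrix glycoproteins rose in 6 of 24 and fell in 11 (7 and 12 adjusted over the list alone; adjusted p = 0.159).

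More genes were called with knockdown in untreated than in TGF-β treated cells, 1844 and 438 against 1052 and 1, but for siMTHFD2-9 the order turned with only the libraries compared (448 against 1500) and with array weights (1603 against 2195). A test of the difference itself is the interaction, with 286 and 0 genes (limma; 2080 and 1636 at an unadjusted p below 0.05). The siControl untreated library 2, with more ribosomal protein transcripts, may have added to it: without it 23 genes were called with siMTHFD2-11, which met the bound set beforehand. That was left open, by a criterion added after the values were seen, because leaving out siMTHFD2-11 untreated library 2 or 3 or siControl untreated library 3 gave 5, 29 or 55. Scaling stayed open as well, with 227 genes after median-ratio rescaling, between the bounds set beforehand, although 439 were called after quantile normalization. With siMTHFD2-11 either count stood against 1 gene with TGF-β. With siMTHFD2-9 the untreated count also stayed the higher, 1914 against 1282 after median-ratio rescaling and 2121 against 1169 after quantile normalization. Without siControl untreated library 2, however, it was 1055, near the 1052 with TGF-β from all libraries. Leaving out a library lowered the TGF-β count too, to 646 without siControl TGF-β library 2. The part of siControl untreated library 2 thus stayed open for siMTHFD2-9 as well. No biological explanation was tested.

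For the TGF-β comparisons in siControl, siMTHFD2-9 and siMTHFD2-11 cells, 10 splits were too few for a share under 0.05, and in each the real split (7971, 7429 and 8240 genes) was the 1 with as many, the highest other giving 0. The same holds for siMTHFD2-9 in untreated cells (1844, highest other 181) and in TGF-β treated cells (1052, highest other 0), and for siMTHFD2-11 in untreated cells (438, highest other 0). For siMTHFD2-11 in TGF-β treated cells 2 of 10 splits gave as many (1, highest other 1). For both siRNAs in untreated cells 2 of 100 splits gave as many genes as the 259, a share under 0.05, the highest other giving 438. These splits ask whether the 3 groups differ, so that share does not show that the siRNAs had an effect in common. With TGF-β 4 of 100 gave as many as the real 1, the highest other giving 663, many times the real count. A count of 1, MTHFD2 itself, says nothing here about chance. The splits with 438 and 663 genes put the 3 siMTHFD2-9 libraries in the place of siControl, which points to the structure of the samples. With siMTHFD2-9 and siControl exchanged whole, 496 genes changed the same way in untreated cells, more than the 259, and 654 with TGF-β. With siMTHFD2-11 and siControl exchanged, 47 and 1 did. For the interaction with siMTHFD2-11 and with both siRNAs, where limma called 0 genes (1636 at an unadjusted p below 0.05 with siMTHFD2-11), all 100 of 100 splits must give as many, so the splits say nothing about chance there, the highest others giving 2 and 21.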
